A study of Homo sapiens with 30 samples.

How the data were processed

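RNA sequencing of 30 libraries from the human astrocytoma line SW1783 was analysed. Cells had been kept for 24 h with aqueous ethanol extracts of Soshiho-tang, Yijin-tang, Okbyeongpung-san or Soyo-san at 500, 100 or 20 µg/mL, or with DMSO as vehicle. Per the labels' protocols, RNA with an integrity number above the submitters' minimum was made into directional libraries with an MGI kit and sequenced as paired ends on an MGI instrument. The sample labels and the series description give different DMSO concentrations for the vehicle, and the difference could not be settled. Water extracts and a wortmannin control named in the series description were not analysed here.

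The deposited table holds estimated counts (expected counts) per Ensembl gene, which the authors made with RSEM 1.3.3 after alignment with STAR 2.7.3a, trimming with Trim Galore 0.6.5 and quality control with FastQC 0.11.9, per the submitters' processing notes. The same notes name hg38 and GRCh38 as the genome build. The annotation release and the strand setting of the counting, and whether they were the same for all libraries, were not given in the sources used here, so reads of overlapping, antisense, read-through and near-identical genes cannot be told apart with certainty. The values were not normalised, and 10.6% to 10.73% of them in the vehicle libraries and 9.24% to 10.09% in the other 27 were not whole numbers. RSEM divides reads that match several genes or transcripts. All values were rounded to whole counts before testing. The table has 60675 gene entries, of which 57055 matched a gene of GENCODE v29 by identifier. Symbols and coordinates (GRCh38) were taken from that release, whose build carries the same name as the build in the notes. Every column was matched to a library by its title. The table also has 30 blank columns, which hold nothing.

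Total estimated counts per library ran from 23.9 to 33.1 M with a median of 27.4 M. At these totals a gene at 1 CPM (count relative to the library total in M) rests on more than 20 reads in each library. Samples were grouped by the extract and concentration in their labels. Among the 24 pairs of libraries of one group, chi-square per degree of freedom over genes with a summed count of at least 40 lay between 3.21 and 39.47, so no pair differed by so little that it looked like one library deposited more than once.

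Genes were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with limma 3.58.1. Library sizes were scaled by TMM, and low genes were removed with filterByExpr at a minimum count of 10 and a minimum total of 15. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes with an adjusted p under 0.05 are called changed. A single fit held the vehicle and the 6 groups of Soshiho-tang and Yijin-tang (21 libraries). Okbyeongpung-san was fitted with the vehicle alone (9 libraries), because it has fewer libraries per group and belongs to another library set. Dose trends were fitted within one extract (9 libraries each) as the slope per 5-fold step in concentration. Fold changes are log2 values with their standard error (SE), and levels are TMM-scaled CPM with their SD. Soyo-san, with 1 library per concentration, was described without a test: log2 ratios of CPM + 1 to the vehicle mean, and medians of gene lists as a percentile among 10000 random lists of the same size drawn from genes of like expression.

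Gene lists were tested with camera at a preset inter-gene correlation of 0.01 and again with the correlation estimated from the data. The 31 lists of pathways, complexes and cell type markers were fixed together with the groups, the tests, the alternative settings and the rule for named genes before the data were examined. A list needed 5 measured members, so leukocyte markers, with 4, were counted but not tested. Counts of list members are given as adjusted over all genes and as adjusted over the list alone.

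Named genes were taken by rule. For each comparison of a 500 µg/mL group with vehicle, and for Soshiho-tang against Yijin-tang at 500 µg/mL, the rule took the 12 highest and 12 lowest fold changes among changed genes with at least 1 CPM in the higher group and no overlap between the libraries of both groups. For other comparisons it took 5 on each side, and for dose trends 5 on each side without the condition on overlap. From every list called by camera, and from the lists of aryl hydrocarbon receptor (AhR), NRF2 and ATF4 targets, it took up to 4 changed members with the largest fold changes. GFAP, S100B and VIM were named as glial markers. For Soyo-san it took the 8 highest and 8 lowest ratios among genes with at least 10 CPM. Genes without a gene symbol are left out of the text. Some genes that the rule takes are not reported here.

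The test was tried on simulated data made from the real means and library sizes with 200 changed genes, all drawn from genes with mean counts well above the filter on low counts. For Soshiho-tang at 500 µg/mL against vehicle (16872 genes), edgeR recovered 46% of genes changed 1.25-fold, 90% of those changed 1.5-fold, 98% of those changed 2-fold and 100% of those changed 4-fold, and 4% of its calls were false. For Okbyeongpung-san at 500 µg/mL against vehicle (16643 genes) the shares were 12%, 64%, 96% and 100%, with 7.5% of calls false. For the dose trend of Soshiho-tang (16370 genes) they were 90%, 100%, 100% and 100%, with 4.9% false. In the trend each fold was applied per 5-fold step in concentration, so its shares cannot be set against those of the group comparisons. DESeq2 1.42.0, run on the same filtered genes, gave 8.7%, 16.4% and 11.8% false calls. Camera called the mitosis list when its genes were raised 1.25-fold (adjusted p = 3.11e-78 in the Soshiho-tang design and 1.18e-33 in the Okbyeongpung-san design) and 0 of 29 other lists in either design. Genes were simulated independently, so this cannot show false calls of lists whose genes vary together.

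Settings chosen beforehand and varied one at a time were RLE size factors, no filter on low counts, a replicate block, a fit of only the compared groups, a fit of all 27 replicated libraries for Okbyeongpung-san, an estimated inter-gene correlation and leaving out each library in turn. DESeq2 was also planned, with its own independent filtering in place of the filter on low counts, so that test and filter changed together, and DESeq2 on the filtered genes was added after the data had been seen. Comparisons of 500 with 20 µg/mL within an extract, list tests at 20 µg/mL, and a correction of each library for GC content and transcript length (lowess, span 0.3) were added after the data had been seen, because the library names put the 3 vehicle libraries in a set that holds no treated library. A pseudocount of 5 and RLE size factors for Soyo-san, and all settings for the overlap between extracts, were also added then. Each comparison between groups of 3 libraries was repeated on all 10 splits of its 6 libraries, and each trend on 100 draws.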

Results

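The series collects transcriptome responses to herbal decoctions that traditional Korean medicine links to Qi. SW1783, an established human astrocytoma line, was kept for 24 h with ethanol extracts of 4 decoctions, and gene expression was measured by RNA sequencing in 30 libraries. Soshiho-tang and Yijin-tang had 3 libraries at each of 500, 100 and 20 µg/mL. Okbyeongpung-san had 2 libraries and Soyo-san 1 library at each of these concentrations, and 3 libraries came from cells given the DMSO vehicle. Total estimated counts per library lay between 23.9 and 33.1 M. The labels do not say that the libraries of a group came from separate cultures, so all p-values measure only the spread between these libraries, which may be technical. Library names put the 3 vehicle libraries in a set of their own, and no contrast with vehicle could be made within a set. Soshiho-tang, Yijin-tang and Okbyeongpung-san are therefore described against vehicle and also at 500 against 20 µg/mL of the same extract, and Soyo-san against vehicle alone. The expression of GFAP, the intermediate filament of astrocytes, did not exceed 0.205 CPM in any library, and that of S100B, a calcium-binding glial protein, did not exceed 0.25 CPM. Both were too low to test. VIM, the intermediate filament vimentin, stood at 5030 ± 45.2 CPM in vehicle (SD, n = 3). For each gene given here with a contrast between groups, all libraries of one group lay above all libraries of the other unless stated. Chance gives such a separation in 10% of cases with 3 against 3 libraries, and more often in comparisons of Okbyeongpung-san, with 2 libraries per concentration.

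Soshiho-tang at 500 µg/mL raised stress genes and lowered matrix genes against vehicle. GDF15 (chromosome 19:18374731-18389176), a stress-induced cytokine, rose from 3.37 ± 0.275 to 51 ± 6.41 CPM (SD, n = 3 each; log2 fold change 3.91 ± 0.13 SE, adjusted p = 1.84e-15). HMOX1 (22:35380361-35394214), which encodes the heme-degrading enzyme heme oxygenase 1, rose from 57.3 ± 2.53 to 408 ± 26.8 CPM (2.82 ± 0.06, adjusted p = 4.12e-19). THBS1 (15:39581079-39599466), the matrix glycoprotein thrombospondin 1, fell from 1990 ± 135 to 579 ± 51.2 CPM (-1.79 ± 0.07, adjusted p = 2.91e-14). Of 24 measured targets of ATF4, the transcription factor of the integrated stress response, 21 rose and 1 fell (21 and 1 adjusted over the list alone; camera adjusted p = 4.13e-18). Besides GDF15 they included the pseudokinase TRIB3 (20:362835-397559; 2.36 ± 0.08), the stress-response regulator NUPR1 (1.98 ± 0.11) and CHAC1, an enzyme that degrades glutathione (1.71 ± 0.10). Of 26 targets of NRF2, the regulator of antioxidant genes, 19 rose and 1 fell (20 and 1 over the list alone; adjusted p = 1.12e-12), among them the autophagy receptor SQSTM1 (1.5 ± 0.05, to 1550 ± 59.7 CPM) and the cystine transporter SLC7A11 (1.26 ± 0.07). Of 28 extracellular matrix genes, 26 fell and 0 rose (27 and 0 over the list alone; adjusted p = 4.13e-18), including the collagens COL1A1 (-1.25 ± 0.06, from 3920 to 1660 CPM), COL1A2 (-1.22 ± 0.06) and COL3A1 (-1.27 ± 0.07).

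Further groups moved in the same comparison. Among 28 genes of the hypoxia response and glycolysis, 22 fell and 3 rose (23 and 3 over the list alone; adjusted p = 2.91e-10). The oxygen-sensing hydroxylase EGLN3 (-2.18 ± 0.15), carbonic anhydrase CA9 (-1.36 ± 0.08) and the glucose transporter SLC2A1 (-1.04 ± 0.05) were lower. Of 30 mitotic genes 24 fell and 0 rose, the same over the list alone (adjusted p = 1.3e-08). MKI67 (10:128096659-128126385), a marker of cycling cells, went from 396 ± 29.6 to 187 ± 16.1 CPM (-1.09 ± 0.13, adjusted p = 1.05e-06), and the mitotic kinesin KIF20A fell by 0.96 ± 0.07 on the log2 scale. Contractile targets of YAP and SRF fell in 14 of 17 and rose in 1 (14 and 1 over the list alone; adjusted p = 5.53e-07), among them the matricellular factor CCN2 (-0.88 ± 0.07). Inflammatory genes moved both ways, with 12 of 22 up and 4 down (13 and 4 over the list alone; adjusted p = 0.0043): the chemokines CXCL8 (1.62 ± 0.13) and CXCL5 (1.97 ± 0.31) rose while CCL2 (-1.51 ± 0.15) fell. The endothelin precursor gene EDN1 (-2.35 ± 0.17) was among the genes with the largest changes. VIM fell by 0.2 ± 0.06 on the log2 scale (adjusted p = 0.0128), a call that was lost without replicate 3 at 500 µg/mL. PHLDA1-AS1, an antisense gene whose reads cannot be assigned with certainty, was at 0 CPM in every vehicle library and at 2.92 ± 0.872 CPM with the extract.

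By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 7407 of 16872 genes differed between Soshiho-tang at 500 µg/mL and vehicle, 3851 higher and 3556 lower, and 761 of them at least 2-fold. Camera called 19 of 30 lists, 7 up and 12 down, and 12 with an estimated correlation. All lists named above were among the 12. Mitochondrially encoded transcripts fell in 12 of 13 (12 over the list alone), with adjusted p = 2.84e-05 and adjusted p = 0.241 with an estimated correlation. Vehicle libraries held 10.47% to 10.7% mitochondrial counts, and the Soshiho-tang libraries at 500 µg/mL held 6.93% to 7.79%.

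The stress response to Soshiho-tang also stood out within its own library set. GDF15 was at 3.31 ± 0.363 CPM at 20 µg/mL and rose by a log2 fold change of 3.95 ± 0.12 at 500 µg/mL (adjusted p = 9.09e-16), and HMOX1 rose from 57.6 ± 1.46 CPM (2.83 ± 0.06, adjusted p = 3.46e-19). HMOX1 averaged 71.6 CPM at 100 µg/mL. DDIT3, a transcription factor of the stress response, rose by 1.88 ± 0.08, and the lysosomal glycoprotein gene GPNMB by 1.73 ± 0.12. THBS1 fell by 1.67 ± 0.07 and COL1A2 by 1.04 ± 0.06. INSIG1, a sterol-sensing regulator, fell by 0.72 ± 0.04. Of 24 ATF4 targets 21 rose and 1 fell (22 and 1 adjusted over the list alone; camera adjusted p = 5.49e-29), and of 26 NRF2 targets 20 rose and 0 fell (21 and 0; 1.32e-18). Of 24 autophagy and lysosome genes 18 rose and 1 fell (20 and 2 over the list alone; 2.33e-11). Mitotic genes fell in 28 of 30 (28 over the list alone; 9.46e-20), matrix genes in 24 of 28 (24; 3.23e-19), YAP and SRF targets in 16 of 17 (17; 2.97e-12), and cholesterol synthesis genes in 16 of 25 (17; 1.75e-09), with 0 higher in each. Mitochondrially encoded transcripts passed the test in 0 of 13 by edgeR, also over the list alone, and camera gave adjusted p = 0.903 for a median log2 fold change of -0.06.

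In this comparison, chosen after the data had been seen, 4868 of 16872 genes differed between 500 and 20 µg/mL of Soshiho-tang, 2464 higher and 2404 lower. Camera called 18 lists, 12 of them also with an estimated correlation, and the 7 lists just named as changed were among the 12. The planned dose trend called 4079 of 16370 genes (2072 up, 2007 down). Its steepest gene was GDF15 at 2.23 ± 0.22 per 5-fold step (adjusted p = 0.000403). GDF15 averaged 3.31, 4.3 and 51 CPM at 20, 100 and 500 µg/mL, so its rise lay mostly in the last step. Its libraries at 20 and 100 µg/mL overlapped. In the trend 21 of 24 ATF4 targets rose (22 over the list alone) while 26 of 30 mitotic genes fell (28 over the list alone). The trend count dropped to 2443, 2247 and 2468 without replicates 1, 2 and 3 of the 500 µg/mL group.

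**Figure D1:**
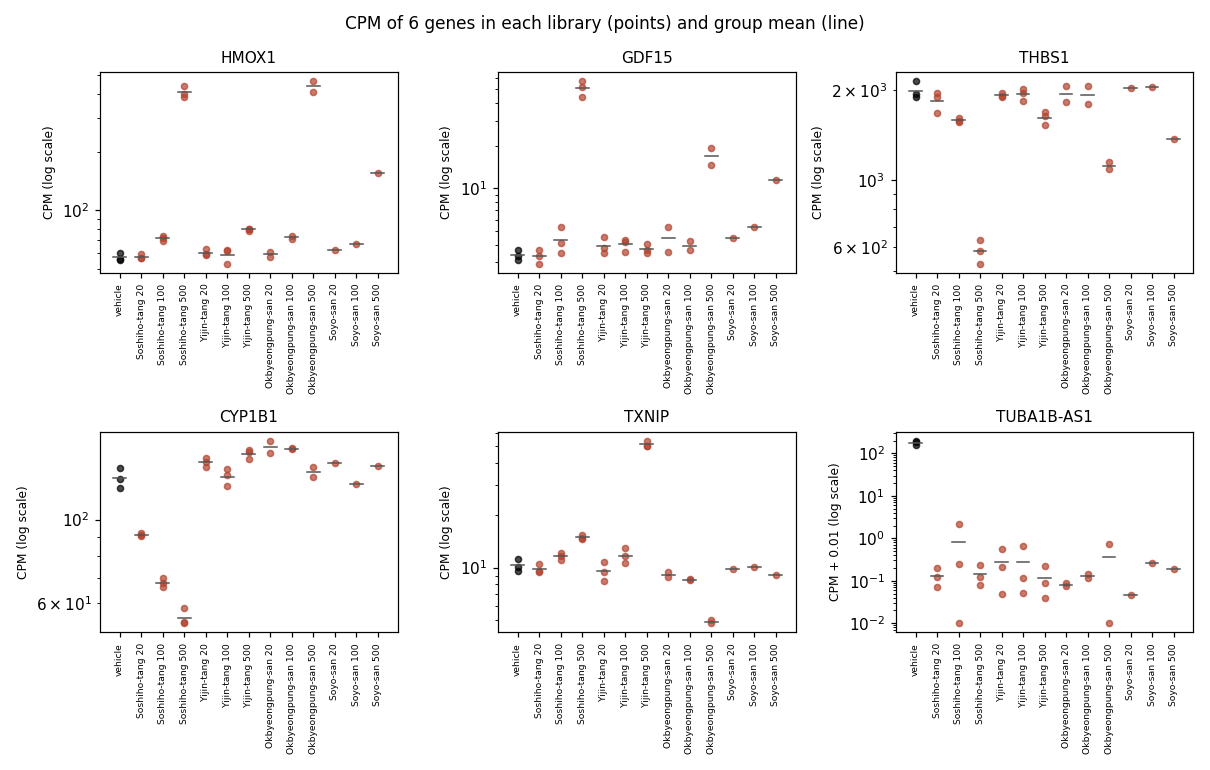
Expression of 6 genes in every library, in CPM on a log axis, with the groups on the horizontal axis (vehicle, then 20, 100 and 500 µg/mL of each extract); points are libraries, lines are group means, and the TUBA1B-AS1 panel shows CPM + 0.01. GDF15 and HMOX1 reach 51 and 408 CPM on average at 500 µg/mL of Soshiho-tang against 3.37 and 57.3 CPM in vehicle, and TXNIP reaches 51.3 CPM at 500 µg/mL of Yijin-tang against 10.3 CPM.

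Yijin-tang at 500 µg/mL raised TXNIP, mitotic genes and NRF2 targets against vehicle. TXNIP (1:145992435-145996600), which encodes the thioredoxin-interacting protein that limits glucose uptake, rose from 10.3 ± 0.831 CPM in vehicle to 51.3 ± 2.19 CPM (SD, n = 3 each; log2 fold change 2.31 ± 0.08, adjusted p = 3.64e-14). Its relative ARRDC4 (15:97960698-97973838) rose from 5.72 ± 0.158 to 15.8 ± 0.485 CPM (1.45 ± 0.10, adjusted p = 2.18e-09). The cytokines IL6 (1.31 ± 0.16, to 8.36 ± 1.36 CPM) and IL11 (0.94 ± 0.09, to 137 ± 10.1 CPM) were higher, and the cardiac actin gene ACTC1 rose by 1.90 ± 0.19. EGR1 (5:138465490-138469315), an immediate early transcription factor, fell from 153 ± 6.01 to 45.4 ± 4.67 CPM (-1.76 ± 0.09, adjusted p = 1.7e-11), and LGR6, a receptor of R-spondins, fell by 2.11 ± 0.16. The mean of EGR1 lay between 32.3 and 53.6 CPM in the groups of every extract at each concentration. Mitotic genes rose in 21 of 30 and fell in 0 (23 and 1 adjusted over the list alone; camera adjusted p = 6.92e-11), with cyclin A2 (CCNA2) at 0.64 ± 0.04 and CDK1 at 0.50 ± 0.07. NRF2 targets rose in 17 of 26 (19 over the list alone; adjusted p = 4.27e-08), led by OSGIN1 at 0.60 ± 0.08. Of 6 measured neuronal markers 4 fell (4 over the list alone; adjusted p = 0.00376), among them the neurofilament gene NEFL (-0.85 ± 0.18). Against the same vehicle, the median log2 ratio of 5 neuronal markers was also below 0 in the single Soyo-san libraries. It was -0.2, -0.23 and -0.13 at 500, 100 and 20 µg/mL, so a lower level was not particular to Yijin-tang. Matrix genes fell in 20 of 28 and rose in 1 (21 and 1 over the list alone; adjusted p = 1.07e-08, and adjusted p = 0.0937 with an estimated correlation).

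Against vehicle, 5274 of 16872 genes differed with Yijin-tang at 500 µg/mL by edgeR's test, 2706 higher and 2568 lower, and 272 at least 2-fold. Camera called 15 lists, 6 up and 9 down. With an estimated correlation 4 calls remained, those of NRF2 targets, mitosis, inflammatory genes and neuronal markers. Inflammatory genes rose in 9 of 22 and fell in 1 (10 and 1 over the list alone; adjusted p = 0.00376). Replicates 1, 2 and 3 at 500 µg/mL held 6.7%, 7.35% and 10.61% mitochondrial counts, against 10.47% to 10.7% in vehicle. Chi-square per degree of freedom was 39.47 and 23.52 for replicate 3 against replicates 1 and 2, and 4.3 between these. Without replicate 3 the count against vehicle was 4916.

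Against 20 µg/mL of the same extract, TXNIP rose from 9.54 ± 1.18 CPM (2.42 ± 0.08, adjusted p = 1.36e-14). SERPINB3, a protease inhibitor, rose by 1.20 ± 0.12, while INSIG1 fell by 0.78 ± 0.04. Of 25 cholesterol synthesis genes 14 fell and 0 rose (16 and 0 adjusted over the list alone; camera adjusted p = 1.8e-18), including MSMO1 (-0.50 ± 0.05) and HMGCS1 (-0.46 ± 0.05), enzymes of the sterol pathway. NRF2 targets rose in 10 of 26 (11 over the list alone; adjusted p = 3.65e-10) and mitotic genes in 8 of 30 (10 over the list alone; adjusted p = 2.64e-10), and YAP and SRF targets fell in 7 of 17 (10 over the list alone; adjusted p = 2.84e-08). In total 951 genes differed between 500 and 20 µg/mL, 455 higher and 496 lower, and 17 lists were called, 6 with an estimated correlation. The 4 lists just named were among these 6. The count of genes was 308 when only these groups were fitted, and it fell to 617 and 519 without replicates 1 and 2 at 500 µg/mL and to 505 and 530 without replicates 1 and 2 at 20 µg/mL. The dose trend called 399 of 16464 genes, 180 up and 219 down, with TXNIP at 1.28 ± 0.14 per 5-fold step (adjusted p = 0.000316) and cholesterol synthesis genes falling in 12 of 25 (16 over the list alone). TXNIP averaged 9.54, 11.8 and 51.3 CPM at 20, 100 and 500 µg/mL, so its rise lay mostly in the last step. Its libraries at 20 and 100 µg/mL overlapped. The trend called 678 genes by DESeq2 with its own filtering and 672 by DESeq2 on the filtered genes, and 168 and 117 without replicates 1 and 2 at 500 µg/mL, and 164 and 202 without replicates 1 and 2 at 20 µg/mL.

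Okbyeongpung-san at 500 µg/mL raised antioxidant and stress genes. HMOX1 rose from 57.3 ± 2.53 CPM in vehicle (n = 3) to 437 ± 37.3 CPM (SD, n = 2; log2 fold change 2.94 ± 0.07, adjusted p = 3.75e-08). SQSTM1 rose by 1.78 ± 0.07, and AKR1C1 (10:4963253-4983283), an aldo-keto reductase whose close paralogs may share its reads, rose by 1.82 ± 0.09. The brain tubulin TUBB4A rose by 3.89 ± 0.21 to 9.29 ± 0.669 CPM, and the kinesin KIF1A by 4.90 ± 0.52 to 1.79 ± 0.0851 CPM. Of 26 NRF2 targets 21 rose and 0 fell (22 and 0 adjusted over the list alone; camera adjusted p = 1.69e-18), and of 24 ATF4 targets 18 rose and 0 fell (18 and 0 over the list alone; adjusted p = 4.25e-11), GDF15 by 2.34 ± 0.18. DNA replication genes fell in 14 of 28 (18 over the list alone; adjusted p = 1.9e-07), mitotic genes in 13 of 30 (16 over the list alone; adjusted p = 1.9e-07), matrix genes in 17 of 28 (21 over the list alone; adjusted p = 1.36e-10) and YAP and SRF targets in 11 of 17 (14 over the list alone; adjusted p = 1.36e-06), with 0 higher in each. Mitochondrially encoded transcripts fell in 12 of 13 (12 over the list alone; adjusted p = 6.3e-13), and mitochondrial counts were 5.68% and 6.8% of the libraries against 10.47% to 10.7% in vehicle. PPP2R2C, a phosphatase subunit, was at 0 CPM in every vehicle library and at 1.1 ± 0.27 CPM with the extract. VIM stood at 4250 ± 753 CPM (-0.24 ± 0.10, adjusted p = 0.129). It passed the test without a filter, with GC and length correction, in a fit of 27 libraries and without Okbyeongpung-san replicate 3, lower than vehicle each time.

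The test called 4113 of 16643 genes for Okbyeongpung-san at 500 µg/mL against vehicle, 2209 higher and 1904 lower. Camera called 17 lists, of which 7 were also called with an estimated correlation, namely the 7 just described. The titles put 1 library per concentration in batch D and 1 in batch E, too few for a test within a batch, and all vehicle libraries carry batch E. The gene count was 2488 and 2513 without vehicle replicates 2 and 3, and 2228 without Okbyeongpung-san replicate 2 at 500 µg/mL.

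Against 20 µg/mL of Okbyeongpung-san, HMOX1 rose from 59.2 ± 2.8 CPM (2.88 ± 0.09, adjusted p = 1.97e-07; n = 2 each), and TUBB4A from 0.243 ± 0.0207 to 9.29 ± 0.669 CPM (5.22 ± 0.28, adjusted p = 8.98e-06). NDRG1, a stress-responsive gene that hypoxia induces, rose by 1.45 ± 0.08, and CCL2 fell by 1.45 ± 0.23. The inducible HSP70 genes HSPA1B (1.41 ± 0.10) and HSPA1A (1.06 ± 0.11), near-identical copies that share reads, rose within a heat shock list of 16 in which 4 rose (9 over the list alone; adjusted p = 5.05e-05, and adjusted p = 0.142 with an estimated correlation). Of 26 NRF2 targets 21 rose (22 over the list alone; adjusted p = 1.65e-23), of 24 ATF4 targets 18 rose (19 over the list alone; adjusted p = 1.41e-15), and of 30 mitotic genes 21 fell (26 over the list alone; adjusted p = 1.72e-17). This comparison called 1716 genes, 867 higher and 849 lower, and 18 lists, 7 with an estimated correlation, the last 3 named lists among them. The gene count was 2604 without a filter, 3082 in a fit of 27 libraries and 2689 with GC and length correction, and 838 and 630 without replicate 2 at 500 and at 20 µg/mL.

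Soshiho-tang and Yijin-tang were compared at equal concentrations, within one library set. At 500 µg/mL GDF15 was at 51 ± 6.41 CPM with Soshiho-tang and 3.74 ± 0.286 CPM with Yijin-tang (log2 difference 3.77 ± 0.12, adjusted p = 2.05e-15; n = 3 each), and HMOX1 at 408 ± 26.8 and 79.6 ± 1.22 CPM (2.36 ± 0.06, adjusted p = 9.14e-18). The cytochrome P450 genes CYP1A1 (15:74719542-74725610; -2.12 ± 0.27) and CYP1B1 (2:38066973-38109902; -1.45 ± 0.05, 54.8 ± 2.83 against 150 ± 4.03 CPM) were lower with Soshiho-tang, as was TIPARP (-0.89 ± 0.05). All 3 are induced by AhR, a receptor for aromatic compounds, and 6 of 8 measured AhR targets were lower and 1 higher (6 and 1 adjusted over the list alone; camera adjusted p = 8.94e-05). Every one of 30 mitotic genes was lower with Soshiho-tang (30 over the list alone; adjusted p = 3.31e-29), with KIF20A at -1.15 ± 0.07 and CCNA2 at -0.86 ± 0.04. ATF4 targets were higher in 21 of 24 and lower in 2 (21 and 2 over the list alone; adjusted p = 1.27e-24), and autophagy and lysosome genes higher in 17 of 24 and lower in 2 (19 and 2; 4.56e-10). The transcription factor PRDM1 (-1.94 ± 0.08) and the glucocorticoid-induced KLF9 (-0.94 ± 0.04) were lower. VIM did not pass the test and its libraries overlapped (0.02 ± 0.06, adjusted p = 0.857).

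At 500 µg/mL 4255 of 16872 genes differed between the 2 extracts by edgeR's test, 2102 higher and 2153 lower with Soshiho-tang, and 14 lists, 5 up and 9 down. With an estimated correlation 12 lists were called, those named above included. At 100 µg/mL 127 genes differed, 46 higher and 81 lower, and CYP1B1 (67.8 ± 1.83 against 130 ± 6.78 CPM; -0.93 ± 0.05, adjusted p = 9.79e-10), CYP1A1 (-1.69 ± 0.28) and CYP2S1 (-0.97 ± 0.11) led the lower side. At 20 µg/mL 22 genes differed, 4 higher and 18 lower, with CYP1B1 at 91.1 ± 0.744 against 142 ± 4.03 CPM (-0.65 ± 0.05, adjusted p = 7.52e-07) and TIPARP at -0.51 ± 0.05. AhR targets were lower in 5 of 8 at 100 µg/mL (7 lower and 1 higher adjusted over the list alone) and in 4 of 8 at 20 µg/mL (7 over the list alone). In vehicle CYP1B1 was at 129 ± 8.43 CPM, CYP1A1 at 1.16 ± 0.0545 CPM and TIPARP at 43.4 ± 1.89 CPM. At 20 µg/mL TIPARP averaged 44.4 CPM with Soshiho-tang, near vehicle, and 62.9 CPM with Yijin-tang. It averaged 67 CPM with Okbyeongpung-san and was at 63.1 CPM in the 1 Soyo-san library at that concentration. Since the vehicle libraries form a set of their own, which of the 2 extracts moved TIPARP cannot be told. The count at 100 µg/mL was 396 without a filter, 193 by DESeq2 on the filtered genes and 46 when only these groups were fitted, and 72, 61 and 80 without Soshiho-tang replicates 1, 2 and 3 and 76 without Yijin-tang replicate 1. At 20 µg/mL it was 252 without a filter, 56 by DESeq2 with its own filtering and 58 on the filtered genes, 34 with GC and length correction and 6 when only these groups were fitted. Leaving out libraries at 20 µg/mL gave 11, 8 and 13 without Yijin-tang replicates 1, 2 and 3, and 10 and 38 without Soshiho-tang replicates 2 and 3.

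**Figure D2:**
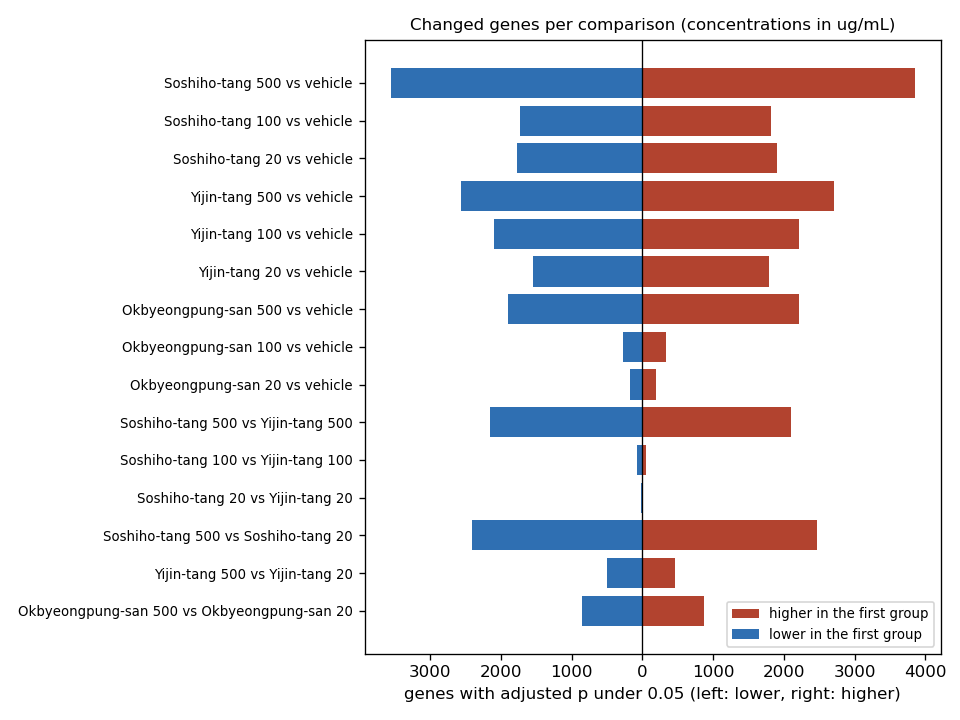
Number of changed genes (horizontal axis, adjusted p under 0.05 by edgeR) for each comparison between groups (vertical axis), with bars for genes higher and genes lower in the group named first. Counts against vehicle run from 372 for Okbyeongpung-san at 20 µg/mL to 7407 for Soshiho-tang at 500 µg/mL, and Soshiho-tang and Yijin-tang differ in 4255, 127 and 22 genes at 500, 100 and 20 µg/mL. Okbyeongpung-san had 2 libraries per concentration and a separate fit of 9 libraries, against 3 and a fit of 21 for the others. Its counts therefore cannot be set directly against theirs.

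Lower concentrations also differed from vehicle in many genes. EGR1 fell from 153 ± 6.01 CPM in vehicle to 36.9 ± 3.46 CPM with Soshiho-tang at 20 µg/mL (log2 fold change -2.07 ± 0.09, adjusted p = 1.44e-12) and to 38.5 ± 3.6 CPM with Yijin-tang at 20 µg/mL (-1.99 ± 0.09, adjusted p = 3e-12). Of 17 immediate early genes, 12 fell with Soshiho-tang (12 adjusted over the list alone; camera adjusted p = 1.05e-07, and adjusted p = 0.0527 with an estimated correlation). With Yijin-tang 10 fell and 1 rose (10 and 1 over the list alone; adjusted p = 4.45e-05, and adjusted p = 0.197 with an estimated correlation). The mitochondrially encoded MT-ND6 fell by 1.31 ± 0.19 with Soshiho-tang and fell by 0.94 ± 0.19 with Yijin-tang at 20 µg/mL on the log2 scale. Mitochondrial counts made up 6.37% to 9.03% of the Soshiho-tang and 7.15% to 9.59% of the Yijin-tang libraries at 20 µg/mL, against 10.47% to 10.7% in vehicle. C7orf25 rose by 1.27 ± 0.15 with Soshiho-tang at 20 µg/mL. TUBA1B-AS1 (12:49127782-49147869), annotated antisense to a tubulin gene, was at 160 to 198 CPM in the 3 vehicle libraries and at no more than 2.14 CPM in the other 27, a value that is uncertain without a stated strand setting. The sources used here do not say whether the vehicle libraries were counted with the same annotation and settings as the others, and any difference would enter every contrast with vehicle. Values that were not whole numbers made up 10.6% to 10.73% in the vehicle libraries and 9.24% to 10.09% in the other 27. At 20 µg/mL the AhR list was the 1 list called with an estimated correlation for Soshiho-tang (5 of 8 lower, 6 over the list alone; adjusted p = 8.61e-05, and adjusted p = 0.0138 with an estimated correlation), of 9 called with the preset one. For Yijin-tang 9 lists were called with the preset correlation and 0 with an estimated one by camera.

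Across genes, which are not independent replicates, fold changes of Soshiho-tang at 20 µg/mL against vehicle correlated with GC content at a Spearman coefficient of -0.43. Against vehicle the test called 3550 genes at 100 and 3680 at 20 µg/mL of Soshiho-tang, 4319 and 3338 for Yijin-tang, and 609 and 372 for Okbyeongpung-san. GC and length correction brought the Soshiho-tang count at 20 µg/mL to 2218, and the count at 100 µg/mL was 2323 without Soshiho-tang replicate 2. The Yijin-tang count at 20 µg/mL was 2081 without vehicle replicate 3 and 2150 without Yijin-tang replicate 3. For Okbyeongpung-san at 100 µg/mL the count was 1727 without a filter, 951 by DESeq2 with its own filtering and 921 on the filtered genes, 148 with GC and length correction and 2494 in a fit of 27 libraries. Its values were 29, 13 and 12 without vehicle replicates 1, 2 and 3 and 12 and 17 without its own replicates 2 and 3. At 20 µg/mL these settings gave 1442, 775 and 728, 180 and 2162, and leaving out libraries gave 26, 20 and 16 for the vehicle and 9 and 9 for its own replicates.

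Genes changed by several extracts overlapped. Between Soshiho-tang and Yijin-tang at 500 µg/mL, 3863 genes were called against vehicle in both, 3582 of them in the same direction (1829 higher, 1753 lower), where independent lists would share 618 and 541. GDF15 and HMOX1 differed between these extracts by their direct contrast. The fold changes correlated across genes, which are not independent replicates, with r = 0.668. Simulated groups with no change that shared the 3 vehicle libraries gave 0.516 on average and at most 0.571 in 20 simulations, and the covariance was 0.185 against at most 0.0492. At 20 µg/mL both extracts shared 2369 calls, 2368 in the same direction (1262 higher and 1106 lower against 202 and 163 for independent lists; r = 0.745, covariance 0.144 against at most 0.0492). Soshiho-tang and Okbyeongpung-san at 500 µg/mL shared 3122 calls, 3061 in the same direction (1574 and 1487 against 508 and 409; r = 0.712, covariance 0.221 against at most 0.0494). Simulated groups shared 0 calls in the same direction by edgeR at the adjusted threshold, which follows from a setting in which no gene was changed. Since 3 vehicle libraries are too few to be divided between the comparisons, part of the excess may come from the shared vehicle. The simulations hold only the spread between libraries. They cannot tell an effect common to the extracts from a difference of the whole vehicle set in preparation or counting.

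Soyo-san had 1 library per concentration, so its values have no replicate check and no test. All Soyo-san titles carry batch D and all vehicle titles batch E, so each ratio also crosses batches. At 500 µg/mL 31 of 9992 genes had a ratio to the vehicle mean of at least 2-fold, 12 higher and 19 lower. At 100 µg/mL 19 of 9922 genes did, 8 higher and 11 lower, and at 20 µg/mL 25 of 9930, 4 higher and 21 lower. The lower side thus did not grow with concentration. Its lowest ratio at 500 µg/mL was that of TUBA1B-AS1 (-7.26, and -7.19 and -7.45 at 100 and 20 µg/mL). With 500 µg/mL GDF15 was at 11.5 CPM against 3.37 ± 0.275 CPM in vehicle (log2 ratio 1.52, and 0.53 and 0.33 at 100 and 20 µg/mL). HMOX1 was at 156 CPM against 57.3 ± 2.53 CPM (1.43, and 0.23 and 0.11), and ANGPTL4, a secreted inhibitor of lipoprotein lipase, had a ratio of 1.26 (0.23 and -0.03). On the low side SAMD11 had a ratio of -1.66, with -0.58 and -0.2 at 100 and 20 µg/mL. EGR1 had ratios of -1.55, -1.52 and -1.89 and MT-ND6 of -1.58, -1.69 and -1.36 at 500, 100 and 20 µg/mL. As a description of this library, the median of 25 NRF2 targets was 0.51 and that of 24 ATF4 targets 0.34, both at percentile 100 among random lists. Inflammatory genes (0.35), interferon-stimulated genes (0.24) and autophagy and lysosome genes (0.17) were also at percentile 100. At 100 and 20 µg/mL the medians were 0.11 and 0.1 for NRF2 targets (percentiles 99.3 and 98.2) and 0.09 and 0.03 for ATF4 targets (percentiles 97.3 and 54.9). The median of 28 matrix genes was -0.26, at percentile 0, and -0.1 and -0.11 at the lower concentrations. That of 13 mitochondrially encoded transcripts was -0.87, -0.83 and -0.91 at 500, 100 and 20 µg/mL, at percentile 0 each.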

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

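Of the tests in this part, the GC and length correction, the comparison of 500 with 20 µg/mL and its thinning, list tests at 20 µg/mL, and the tests of antisense and read-through genes were chosen after the data had been seen. Differences between extracts, tested by the contrast of Soshiho-tang with Yijin-tang itself, drew attention to 4 results: 4255 genes at 500 µg/mL, 127 at 100 µg/mL and 22 at 20 µg/mL, and 14 gene lists at 500 µg/mL.

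The first pattern is the large number of genes that differed between vehicle and even 20 µg/mL of an extract, 3680 for Soshiho-tang and 3338 for Yijin-tang, against 372 for Okbyeongpung-san with fewer libraries. After a GC and length correction 45.3% of the changed genes of Soshiho-tang at 20 µg/mL were still changed, 1667 of 3680, with 1757 of 3338 for Yijin-tang and 99 of 372 for Okbyeongpung-san. The bounds were set for Soshiho-tang before this test was run, though after the data had been seen. The Soshiho-tang share lay between them, the Yijin-tang share above both and the Okbyeongpung-san share below both. These properties could thus account for part of the genes, and how large a part stays open. Fold changes against vehicle of Soshiho-tang and Okbyeongpung-san at 20 µg/mL, which belong to different library sets, had a covariance of 0.136 against at most 0.0508 in simulations, as separate preparation of the vehicle libraries would also give, and every vehicle library is in its own set. Among genes called for Yijin-tang at 20 µg/mL, 54.7% had a Soshiho-tang slope of the same direction, which leaves a response to the extracts open, and this cannot be told apart from the library set.

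The second pattern is the level of TUBA1B-AS1 and of read-through genes in vehicle, such as RPS10-NUDT3 (log2 ratio of vehicle to pooled 20 µg/mL 2.16, adjusted p = 0.00345 by edgeR) and PEDS1-UBE2V1 (1.92, adjusted p = 0.000329). Counting of antisense reads throughout the vehicle libraries would raise noncoding genes opposite expressed coding genes as a class. Their median was 0.02 over 923 genes (SD 0.98, 70 higher and 48 lower in vehicle), which argues against a rise of the whole class. A median cannot show antisense counting limited to a few genes, such as those opposite the most expressed ones, so this stays open for TUBA1B-AS1. Another assignment of shared reads to read-through genes stays open: their median was 0.11 over 79 genes (SD 1.41), with 11 higher and 1 lower in vehicle. Counting of the vehicle libraries with another annotation also stays open and would enter every contrast with vehicle. No biological explanation was tested.

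The third pattern is the difference between 500 and 20 µg/mL of Soshiho-tang, 4868 genes within one library set. GC content and transcript length as the whole cause are argued against by the 93.2% of these genes still changed after the correction. Library depth is argued against by the 91% still changed when every library was thinned to 23.9 M counts. A response to the higher concentration, which the design names, may account for the pattern and stays a hypothesis, and a handling difference between concentrations was not tested.

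With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and in each gene count 1 of the 10, the real one, gave as many genes. Every other split mixes both groups, which widens the spread and shrinks the contrast. Such splits would call few genes whenever the groups differ for any reason, the library set included. The real count and the highest of the other splits were 7407 and 1 for Soshiho-tang at 500 µg/mL against vehicle, 3550 and 3 at 100 µg/mL, and 3680 and 0 at 20 µg/mL. For Yijin-tang they were 5274 and 0, 4319 and 1, and 3338 and 0. For Soshiho-tang against Yijin-tang they were 4255 and 0, 127 and 0, and 22 and 0, and for 500 against 20 µg/mL 4868 and 0 for Soshiho-tang and 951 and 2 for Yijin-tang. Counts of gene lists under the preset correlation were less distinct: 19 and 16 for Soshiho-tang and 15 and 11 for Yijin-tang at 500 µg/mL against vehicle, 9 and 8 for each at 20 µg/mL, and 18 and 14 and 17 and 11 for 500 against 20 µg/mL. For Soshiho-tang against Yijin-tang at 500 µg/mL the counts were 14 and 15, and 3 of the 10 splits gave as many lists. For the dose trends 1 of 100 draws, the real one, gave as many genes, a share under 0.05, which argues against a chance order of these libraries. Draws that mix different groups widen the spread, so most of them could call few genes. A change at 500 µg/mL alone would pass as well, and chance between cultures could not be tested. The real and highest other counts were 4079 and 3376 for Soshiho-tang and 399 and 92 for Yijin-tang. Both of these other draws kept the 3 libraries at 500 µg/mL at the top and mixed the lower concentrations.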

How the results depend on the processing

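No named gene or gene list past its threshold reversed under any alternative, and with RLE size factors every count of changed genes and called lists stayed within 1.5 times. Chosen after seeing the data were the correction for GC and length, DESeq2 on the filtered genes, the settings for Soyo-san and for the overlap between extracts, and every setting of the comparisons of 500 with 20 µg/mL and of the lists at 20 µg/mL. The others were planned. The alternatives foreseen for normalized units were not run, because the values are estimated counts. Except where a setting tests more or fewer genes or libraries, the cause was not tested. With no filter on low counts, Soshiho-tang and Yijin-tang differed in 396 genes at 100 and 252 at 20 µg/mL, Okbyeongpung-san differed from vehicle in 1727 and 1442 genes at 100 and 20 µg/mL, and its comparison of 500 with 20 µg/mL gave 2604. By DESeq2 with its own filtering in place of the filter on low counts the counts were 56 for Soshiho-tang against Yijin-tang at 20 µg/mL, 951 and 775 for Okbyeongpung-san at 100 and 20 µg/mL and 678 for the Yijin-tang trend. On the filtered genes DESeq2 gave 58, 921, 728 and 672 for these, and 193 for Soshiho-tang against Yijin-tang at 100 µg/mL. With GC and length correction they were 2218 for Soshiho-tang at 20 µg/mL against vehicle, 34 for the extracts at 20 µg/mL, 148 and 180 for Okbyeongpung-san at 100 and 20 µg/mL, and 2689 for its 500 against 20 µg/mL. Fitting only the compared groups gave 46 and 6 genes between the extracts at 100 and 20 µg/mL and 308 for Yijin-tang at 500 against 20 µg/mL. The fit of 27 libraries gave 2494, 2162 and 3082 for Okbyeongpung-san at 100 and 20 µg/mL and for its 500 against 20 µg/mL. With an estimated correlation the called lists were 12, 4 and 7 for Soshiho-tang, Yijin-tang and Okbyeongpung-san at 500 µg/mL against vehicle, 6 and 7 for Yijin-tang and Okbyeongpung-san at 500 against 20 µg/mL, and 1 and 0 by camera for Soshiho-tang and Yijin-tang at 20 µg/mL. The number of Soyo-san genes at least 2-fold from vehicle at 500 µg/mL was 22 with a pseudocount of 5, against 31. Named genes were counted once per comparison, as 751 entries. With GC and length correction 708 entries had the same status, called or not, and 42 lost their call. By DESeq2 with its own filtering the numbers were 693 and 20. Entries called in neither fit, such as VIM between Soshiho-tang and Yijin-tang at 500 µg/mL, count as the same status. DESeq2 gave no adjusted p for 38 of the 751, among them 5 and 7 of 10 for Okbyeongpung-san at 100 and 20 µg/mL. On the filtered genes 692 had the same status and 17 lost their call, and 42 had no adjusted p.

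Leaving out each library in turn gave 6395 to 6747, 2323 to 2796 and 2734 to 3022 genes for Soshiho-tang at 500, 100 and 20 µg/mL against vehicle, and 4068 to 4916, 2983 to 4064 and 2081 to 2822 for Yijin-tang. It gave 2228 to 3869, 12 to 29 and 9 to 26 for Okbyeongpung-san, where a group left with 1 library is assumed to vary like the others. Between the extracts it gave 3409 to 3957, 61 to 124 and 8 to 38. For 500 against 20 µg/mL it gave 3814 to 4286, 505 to 1057 and 630 to 1966 for Soshiho-tang, Yijin-tang and Okbyeongpung-san, and for the trends 2247 to 4166 and 117 to 501. Called lists ran from 20 to 23, 12 to 17 and 14 to 18 at 500 µg/mL against vehicle, 6 to 10 and 8 to 12 at 20 µg/mL, 14 to 15 between the extracts, and 17 to 19, 14 to 18 and 17 to 18 for 500 against 20 µg/mL. The report names each library that moved a count by over 1.5 times. Over all these fits named entries had the same status, called or not, 3814 times and lost their call 483 times. For Okbyeongpung-san they kept it 12 times and lost it 38 times at 100 µg/mL, and 10 and 40 times at 20 µg/mL.

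With the replicate number as a block, Okbyeongpung-san at 100 and 20 µg/mL gave 52 and 40 genes against vehicle, and no other count of calls moved by over 1.5 times. Of named entries 722 had the same status, called or not, and 29 lost their call, with 3 kept and 7 lost at each of these concentrations. The block gave 1763 genes for Okbyeongpung-san at 500 against 20 µg/mL, where the titles tie number 2 to batch E and number 3 to batch D. Correlations of same-number pairs lay between -0.17 and 0.16 over 15 comparisons, with every pair over 0.1 in 0 of them, so the numbers were not taken to pair the libraries. Every library correlated best with its own number in 1 of 11 comparisons with 3 pairs, Soshiho-tang at 500 µg/mL against vehicle. For Soyo-san no paired fit could be made, since it has 1 library per concentration and no test.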

Other observations

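With Soshiho-tang at 500 µg/mL against vehicle, 15 of 24 autophagy and lysosome genes rose and 3 fell (15 and 3 adjusted over the list alone; camera adjusted p = 3.65e-05, and adjusted p = 0.043 with an estimated correlation). The cholesterol exporter of lysosomes NPC1 rose from 212 ± 6.16 to 415 ± 6.19 CPM (SD, n = 3 each; log2 fold change 0.95 ± 0.05 SE, adjusted p = 1.01e-11) and the autophagy protein MAP1LC3B by 0.67 ± 0.05. Of 22 ribosome biogenesis genes 12 rose and 0 fell, the same over the list alone (adjusted p = 0.00341, and adjusted p = 0.043 with an estimated correlation), led by NOP16 (0.43 ± 0.08). Heat shock genes fell in 11 of 16 and rose in 2 (11 and 3 over the list alone; adjusted p = 0.00865, and adjusted p = 0.0485 with an estimated correlation). Targets of p53 rose in 11 of 21 and fell in 1 (11 and 1 over the list alone; adjusted p = 0.0076, and adjusted p = 0.043 with an estimated correlation). Of 8 measured astroglial markers 6 fell and 1 rose (7 and 1 over the list alone; adjusted p = 0.00322, and adjusted p = 0.0784 with an estimated correlation). The glutamate transporter SLC1A3 (-0.79 ± 0.07) and the transcription factor SOX9 (-0.59 ± 0.06) fell while nestin (NES, 0.43 ± 0.12) rose. Of 7 measured epithelial markers 4 fell and 1 rose (4 and 1 over the list alone; adjusted p = 0.0435, and adjusted p = 0.0941 with an estimated correlation), a call also lost with GC and length correction. KRT18 (12:52948871-52952901), a keratin with pseudogenes that may take some of its reads, fell from 131 ± 5.23 to 51 ± 1.62 CPM.

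Targets of FOXO transcription factors, which PI3K inhibition activates, moved both ways at 500 µg/mL. Against vehicle 5 of 15 rose and 4 fell with Soshiho-tang (5 and 4 over the list alone; adjusted p = 0.64), 5 rose and 4 fell with Yijin-tang (5 and 6 over the list alone; adjusted p = 0.929), and 3 rose and 4 fell with Okbyeongpung-san (4 and 4 over the list alone; adjusted p = 0.476). Targets of ERK signalling were higher in 9 of 16 and lower in 3 with Soshiho-tang than with Yijin-tang (9 and 3 over the list alone; adjusted p = 0.00277, and adjusted p = 0.034 with an estimated correlation). With Okbyeongpung-san 10 of 16 rose and 2 fell against vehicle (11 and 2 over the list alone; adjusted p = 0.00453, and adjusted p = 0.193 with an estimated correlation).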
